A study of Mus musculus with 6 samples.

How the data were processed

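Gene expression was measured by RNA sequencing in 6 libraries of the mouse line RAW 264.7, 3 labelled LPS (100 ng/mL, 24 h) and 3 labelled LPS plus PE-CUR (100 ng/mL and 2 mg/mL, 24 h). Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit. Per the submitters' processing notes, fastp, HTSeq, SAMtools and DESeq2 were used with the mouse build mm10, and no versions are given. The aligner, the gene annotation and whether counting used strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart with certainty.

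The authors deposited a table of whole-number counts per gene symbol and a table of FPKM values for the same 21604 symbols and 6 libraries. Column names equal the sample titles, which gave each column its group and replicate number. The deposited FPKM values equal the count divided by gene length and library total on the FPKM scale, with 1 length per gene, in 100% of 105337 values above 0 (relative tolerance 0.0001). They are a rescaling of the same counts and not a second measurement. The counts were used for the main tests and the FPKM values for alternatives. Total counts were 28530750 to 35276533 per library, so 1 CPM is about 30 counts in each library, and genes near or below that level have wide errors.

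Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group, which left 13014, and libraries were scaled by TMM factors, which lay between 0.964 and 1.03. A quasi-likelihood model with robust dispersions and the group as its only term was fitted to all 6 libraries, and p-values, two-sided, were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are LPS plus PE-CUR over LPS, their SE is the fold change divided by the root of its F statistic, and levels are CPM scaled by the TMM factors, as mean ± SD of 3 libraries. For transcripts of other tissues, CPM of the unscaled library total is given. Coordinates, counted from 1, come from the RefSeq annotation of GRCm38.p6, the assembly of mm10, in which 20996 of the 21604 symbols were found.

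Fixed gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 5 tested members, and beside it with an estimated correlation and with fry. Shares of counts were compared by exact two-sided permutation tests, for which 3 against 3 libraries cannot give a p below 0.1. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 10 genes with the largest fold change in each direction among those past the threshold with a mean of at least 5 CPM and no overlap of the groups, leaving out predicted genes without an established symbol. It also names 16 genes of inflammation, macrophage activation and osteoclasts whatever their result, and from each described list up to 4 passing members with the smallest p in its majority direction and up to 2 in the other. Members that did not pass are given as values only.

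The test was run on simulated data, with counts drawn for the same genes, means and library sizes and 200 genes changed by known folds. With each gene's own estimated dispersion, 67.2% of 67 genes changed 1.5-fold, 82.1% of 67 changed 2-fold and 97.0% of 66 changed 4-fold were recovered among 12805 genes tested. In that simulation 23 of 187 calls (12.3%) were unchanged genes, above the nominal 5%. With dispersions on the fitted trend, 7 of 174 calls (4.02%) were unchanged genes, among 12782 tested. Calls of genes whose replicates vary far from the trend may thus be less certain than their adjusted p states. The share of 12.3% itself does not carry over to the data, since 200 genes were changed in the simulation and 63.4% of tested genes were called in the data. With 1 of 36 lists shifted by 0.5 on the log2 scale, camera called that list and 1 unshifted list. Each gene was drawn independently there, whereas estimated correlations within lists reached 0.746 in the data. The simulation thus cannot show whether the preset correlation holds for these data.

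The alternatives were median-ratio factors, library size alone, no filter, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and on log2(FPKM + 0.1) for the same genes, limma on log2(FPKM + 1) without a filter, the replicate number as a block, each library left out in turn, and removal of mitochondrial genes and the 10 most abundant genes. For lists they were an estimated correlation, fry, and members with a mean of at least 1 CPM. Offsets for GC content and length, and the removal of tissue marker genes, were added after seeing the data. GC content came from GENCODE M21 transcripts and was known for 93.8% of tested genes. No library was left out of the main tests.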

Results

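RNA was sequenced from RAW 264.7 cells, a mouse macrophage-like line that can form osteoclasts under suitable stimulation. The labels describe a group of 3 samples given lipopolysaccharide (LPS), a bacterial cell wall component that activates macrophages, at 100 ng/mL for 24 h. The other group of 3 samples received LPS at the same dose together with 2 mg/mL PE-CUR for 24 h. The title of the series speaks of curcumin-loaded Pickering emulsions, droplets stabilised by solid particles and loaded with the plant polyphenol curcumin, and PE-CUR is the name of the treatment in the labels. The design text asks about effects against inflammation and against osteoclast formation. The labels name no untreated cells, no empty emulsion, no free curcumin and no osteoclast-inducing cytokine, so every value below is a difference between LPS plus PE-CUR and LPS alone. Total counts per library were 32005736, 32361691 and 35276533 in LPS replicates 1 to 3 and 32248525, 35231076 and 28530750 in LPS plus PE-CUR replicates 1 to 3. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which can be technical.

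All directions below follow the labels. An exchange of labels between the groups cannot be told apart from a response in this design, as weighed in the closing section. Higher in LPS plus PE-CUR were most tested members of the S phase (32 of 32) and mitosis lists (31 of 32). So were most tested members of the interferon-stimulated (30 of 40) and nuclear respiratory chain lists (36 of 38). Most were lower in the lists of lipid uptake and storage genes (18 of 26, 4 higher), NRF2 targets of the oxidative stress response (20 of 32, 4 higher), lysosome genes (22 of 34, 1 higher) and proton pump subunits (14 of 17, 0 higher). As groups, these lists were called by camera with a preset correlation between genes, and for each the adjusted p was at least 0.452 with an estimated correlation. Among the inflammatory genes the direction was divided. Tnf and Nos2 rose while Ptgs2, Il6, Il1a and Cxcl2 fell. Of 13014 genes tested, 4004 were higher and 4252 were lower in LPS plus PE-CUR at a Benjamini-Hochberg adjusted p under 0.05 (edgeR quasi-likelihood test, 3 against 3 libraries), which is 63.4% of the genes tested. At least 2-fold changes were called for 829 higher and 1491 lower genes. Genes with a count numbered 18219, 18210 and 18451 in LPS replicates 1 to 3. In LPS plus PE-CUR replicates 1 to 3 they numbered 16701, 17002 and 16754. Whether this bears on the excess of 2-fold falls was not tested. The median log2 fold change of all tested genes was -0.03. Libraries of the same group correlated at 0.985 or more (Pearson correlation of log2 CPM across genes), libraries of different groups at 0.955 or less, and the first principal component, which separated the groups, held 79.0% of the variance.

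Of 40 gene lists fixed beforehand, 36 had at least 5 tested members, and 14 of these were called by camera with a preset correlation of 0.01 between genes, 6 higher and 8 lower. With the correlation estimated from these libraries camera called 0 lists, 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.452. The rotation test fry called 30 lists for movement in one direction and 36 for change in either direction, which does not compare a list with other genes. The list calls thus rest on the preset form of the test. Correlation between genes is not the whole difference between the preset and the estimated form. The list of alternative activation markers had an estimated correlation of 0.00045, below the preset. Its unadjusted camera p was still 0.0218 with the preset and 0.0703 with the estimate. The loss of calls can thus not be read as an effect of correlation alone. The counts of members that passed the test of single genes are given with each list.

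**Figure D1:**
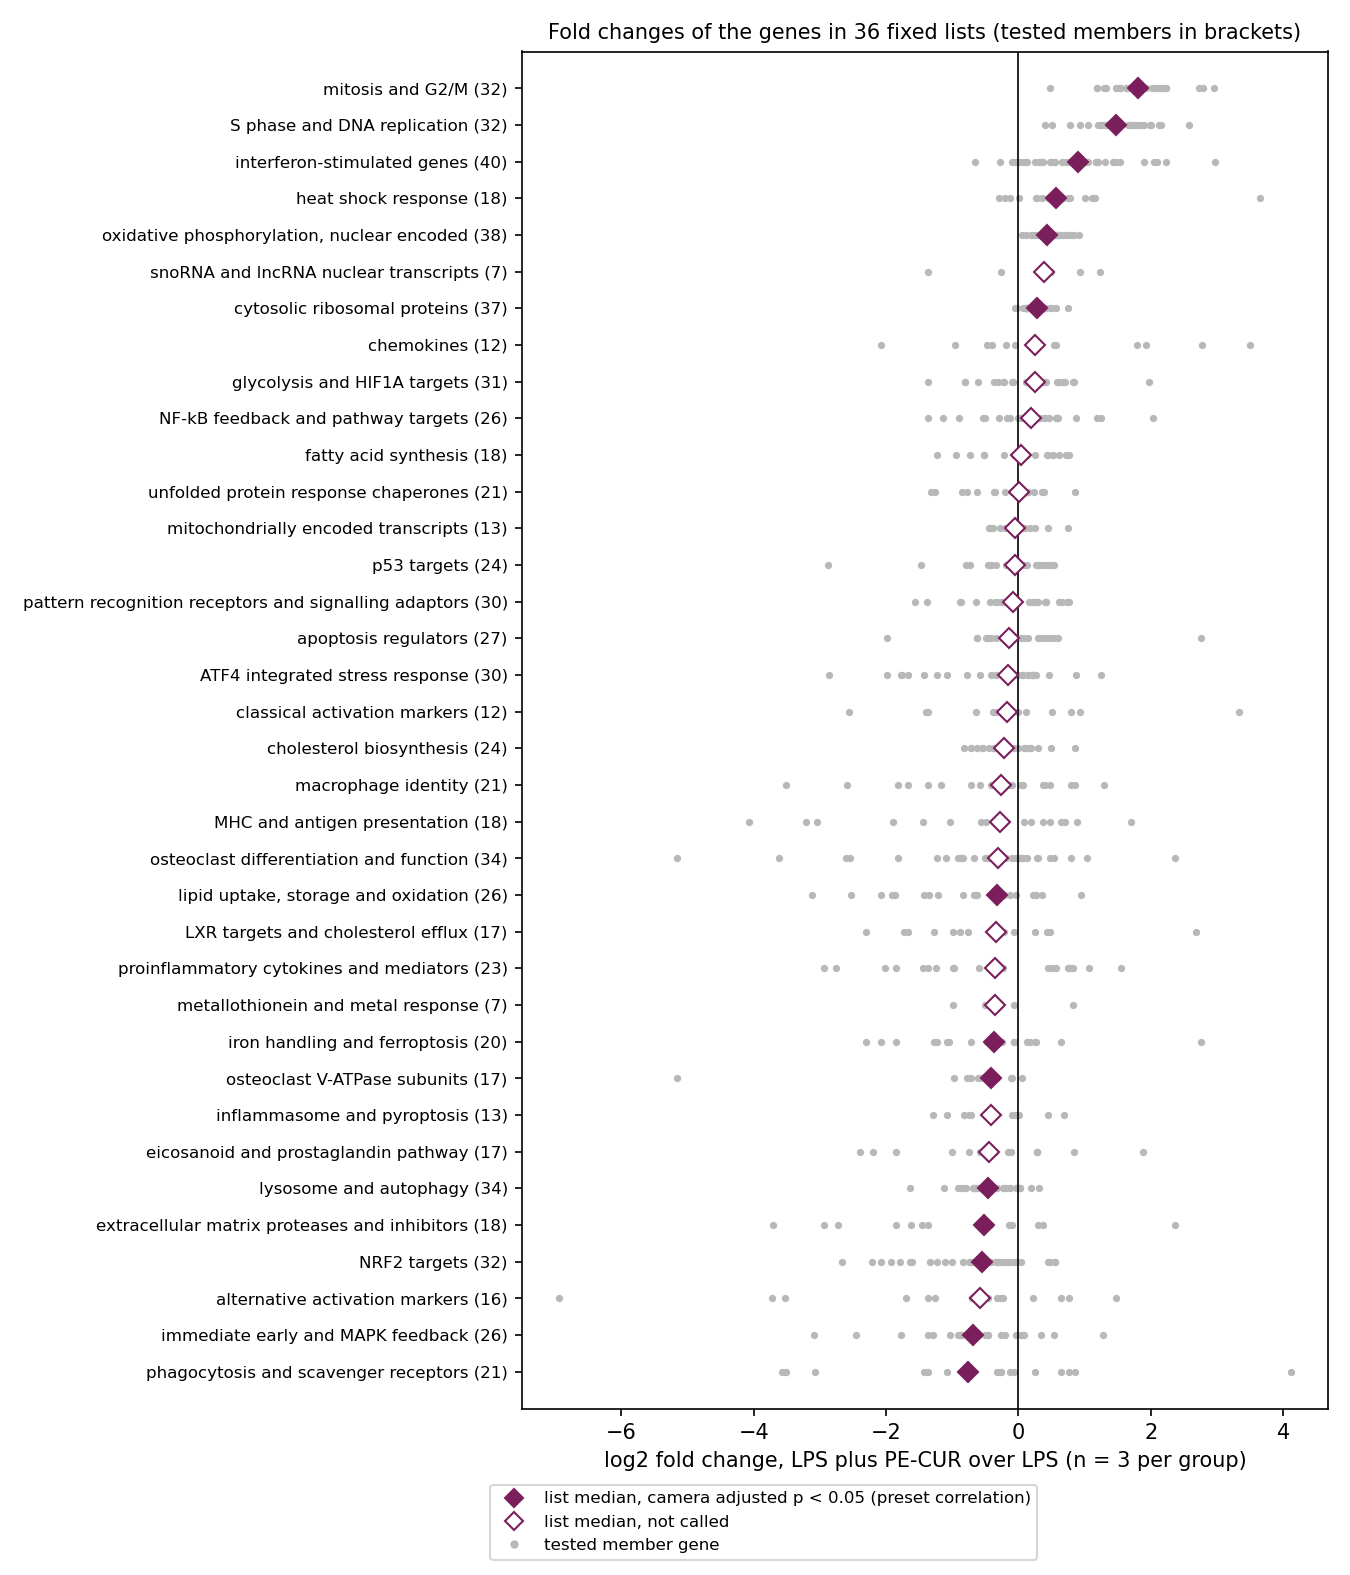
Log2 fold change of LPS plus PE-CUR over LPS (x axis) for the tested members of 36 fixed lists (y axis, number of tested members in brackets), with small dots for genes and diamonds for list medians, filled where camera called the list with the preset correlation. The mitosis list has the highest median at 1.81 and the phagocytosis list the lowest at -0.76.

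The question of inflammation was addressed with lists of cytokines, chemokines, activation markers and NF-kB targets. Tnf, the gene of tumour necrosis factor (chromosome 17, 35199367 to 35202007, build mm10), rose from 546 ± 44.4 to 1139 ± 91.3 CPM (mean ± SD, n = 3; log2 fold change 1.06, SE 0.08, edgeR adjusted p = 8.11e-07). Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960226), rose from 334 ± 41.3 to 577 ± 52.6 CPM (log2 fold change 0.79, SE 0.10, edgeR adjusted p = 1.16e-04). Ptgs2, which makes prostaglandins and is also called COX-2 (chromosome 1, 150100031 to 150108234), fell from 4550 ± 598 to 1265 ± 57.0 CPM (log2 fold change -1.85, SE 0.09, edgeR adjusted p = 1.58e-07). Il6 fell from 1.89 ± 0.422 to 0.245 ± 0.0360 CPM (log2 fold change -2.93, edgeR adjusted p = 2.40e-05) and Il1b from 1.92 ± 0.238 to 0.807 ± 0.168 CPM (log2 fold change -1.24, edgeR adjusted p = 0.00226), so both cytokine genes were near the floor of detection in both groups. In each of these 5 genes the values of the groups did not overlap, which chance gives in 10% of unchanged genes. All 5 loci are protein coding, and Il6 and Il1b overlap other annotated transcripts (A230098N10Rik and Il1bos). Il10, an anti-inflammatory cytokine gene, did not reach the level needed for the test, with 7, 12 and 7 counts in the LPS libraries and 2, 1 and 0 in those with PE-CUR.

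In the list of proinflammatory cytokines and mediators, 6 rose, 13 fell and 4 did not pass of 23 tested members (7 rose and 13 fell adjusted over the list alone). Beside Tnf and Nos2, Hmgb1, a nuclear protein that acts as an alarm signal when released, rose from 20.8 to 61.1 CPM. Il1a fell from 5.81 to 0.848 CPM and Csf1, the growth factor of macrophages, from 19.5 to 7.20 CPM. The list was not called (median log2 fold change -0.35, camera adjusted p = 0.325). Of the 12 tested chemokines 3 rose, 3 fell and 6 did not pass (3 rose and 3 fell adjusted over the list alone). Cxcl2, which attracts neutrophils, fell from 2469 to 582 CPM and Cxcl16 from 18.2 to 9.38 CPM, whereas Cxcl10 rose from 2.22 to 15.1 CPM and Ccl5, which attracts T cells, from 10.3 to 39.2 CPM. Ccl3 stood at 5039 ± 348 CPM in LPS and 4439 ± 448 CPM in LPS plus PE-CUR and did not pass. The chemokine list was not called (median 0.25, camera adjusted p = 0.893). Among 26 NF-kB feedback genes and targets 12 rose, 6 fell and 8 did not pass (13 rose and 6 fell adjusted over the list alone), with Nfkbid, Tnip3, Sod2 and Nfkb1 higher and Cd83 and Tnfaip2 lower (camera adjusted p = 0.162).

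**Figure D2:**
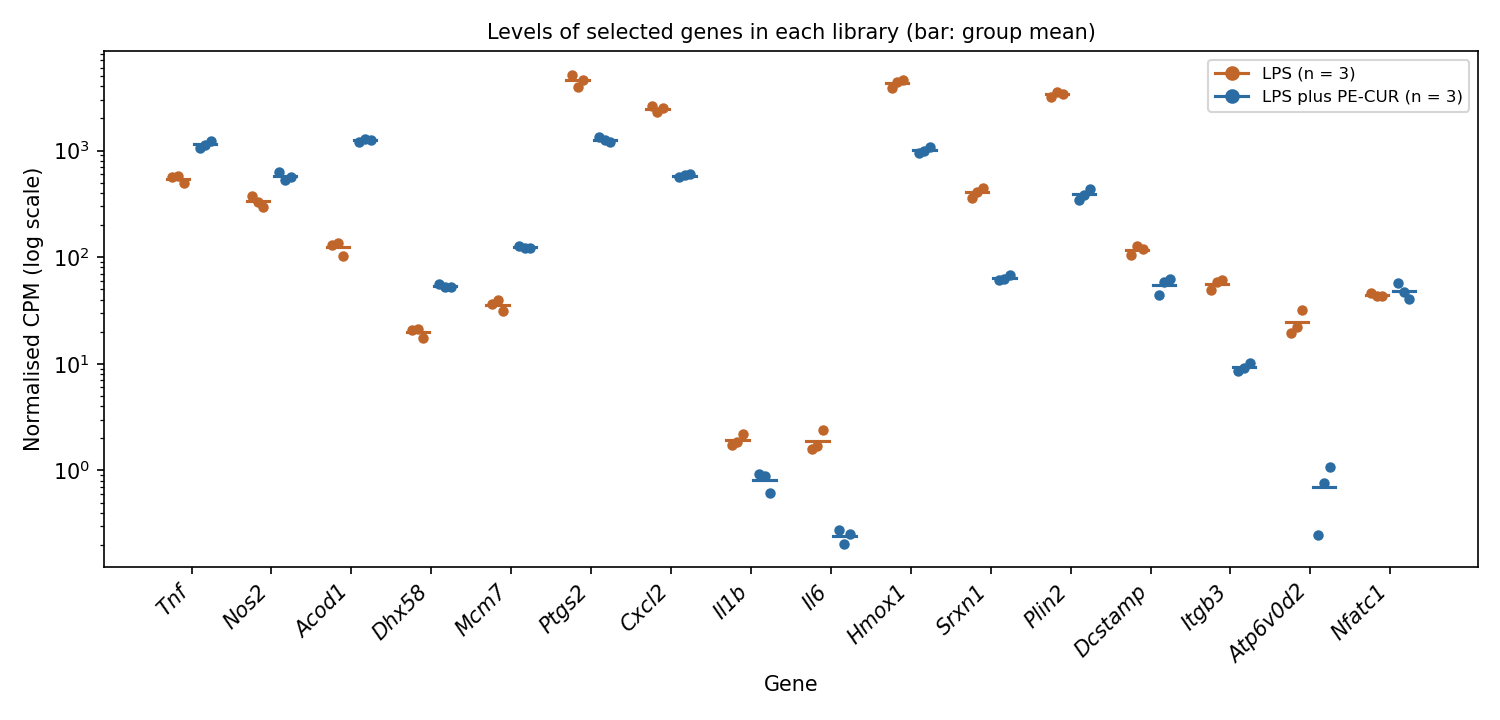
Normalised CPM on a log axis (y) of 16 genes (x) in each of the 3 LPS and 3 LPS plus PE-CUR libraries, with points for libraries and bars for group means. Tnf rises from 546 to 1139 CPM while Ptgs2 falls from 4550 to 1265 CPM, and the points of Nfatc1 overlap between the groups.

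Markers of both classical and alternative macrophage activation were measured. Acod1, which makes itaconate in activated macrophages (chromosome 14, 103047012 to 103056573), rose 10.1-fold from 123 ± 17.2 to 1244 ± 32.2 CPM (log2 fold change 3.33, SE 0.10, edgeR adjusted p = 3.05e-08). Cd86, a costimulatory surface protein, fell from 10.6 to 1.78 CPM and the IgG receptor gene Fcgr1 from 155 to 60.2 CPM. Of 12 tested classical markers 4 rose, 4 fell and 4 did not pass (4 rose and 4 fell adjusted over the list alone), and the list was not called (camera adjusted p = 0.893). Of 16 tested alternative markers 3 rose, 9 fell and 4 did not pass (3 rose and 9 fell adjusted over the list alone), with the lectin genes Clec10a falling from 34.1 to 2.59 CPM, Clec7a from 9.01 to 0.777 CPM and Mgl2 from 3.08 to 0.0219 CPM. The scavenger receptor gene Msr1 rose from 283 to 479 CPM. That list narrowly missed the threshold (median -0.58, camera adjusted p = 0.0521) and passed it under several alternatives. Arg1 (0.599 ± 0.335 CPM in LPS, 0.249 ± 0.380 in LPS plus PE-CUR) and Mrc1 (0.455 ± 0.298 and 0.344 ± 0.595 CPM), markers often used for alternative activation, were at the floor and did not pass (edgeR adjusted p = 0.330 and 0.864). Each passed when 1 library was left out, Arg1 without LPS plus PE-CUR replicate 3 (log2 fold change -1.36 with it and -4.14 without) and Mrc1 without LPS plus PE-CUR replicate 2 (-0.32 with it and -6.86 without). In each case that library held most of the reads of its group. Neither passed in the other fits that left out a library, where Arg1 moved to -0.70 without LPS plus PE-CUR replicate 2 and Mrc1 turned above 0 without LPS replicate 2, LPS plus PE-CUR replicate 1 or LPS plus PE-CUR replicate 3 (at most 0.28). Arg1 is also a liver transcript, and its reads lay mostly in the 4 libraries that held albumin transcripts.

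Of 40 tested genes induced by interferon 30 rose, 0 fell and 10 did not pass (30 rose and 0 fell adjusted over the list alone), with a median log2 fold change of 0.90. The RNA sensor genes Ddx58 and Dhx58 rose from 111 to 208 and from 19.8 to 53.9 CPM. Zbp1, a sensor of nucleic acids, rose from 2.46 ± 0.356 to 19.3 ± 3.10 CPM (log2 fold change 2.98, edgeR adjusted p = 1.51e-07). The list was called with the preset correlation (camera adjusted p = 1.22e-07), and its adjusted p = 0.452 with an estimated correlation. Of 30 pattern recognition receptors and signalling adaptors 12 rose, 10 fell and 8 did not pass (12 rose and 11 fell adjusted over the list alone), with Tlr1, Tlr13, Myd88 and Map3k7 higher and Ly96 and Tab2 lower (camera adjusted p = 0.893). Of 13 inflammasome and pyroptosis genes 1 rose, 7 fell and 5 did not pass (1 rose and 7 fell adjusted over the list alone). Casp4, Nlrc4, Naip2 and Txnip fell and Gsdmd, the pore protein of pyroptosis, rose from 51.7 to 70.3 CPM (camera adjusted p = 0.103).

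The question of osteoclasts was addressed with a list of differentiation and function genes and a list of proton pump subunits. Atp6v0d2, a pump subunit needed for fusion of osteoclast precursors (chromosome 4, 19876838 to 19922566), fell 35.5-fold from 24.4 ± 6.60 to 0.699 ± 0.423 CPM (log2 fold change -5.15, SE 0.43, edgeR adjusted p = 1.35e-04). Dcstamp, a membrane protein of cell fusion (chromosome 15, 39745930 to 39760938), fell from 117 ± 11.6 to 55.2 ± 9.23 CPM (log2 fold change -1.09, SE 0.13, edgeR adjusted p = 2.42e-04). The integrin gene Itgb3 fell from 56.4 to 9.29 CPM, the kinase gene Src from 33.6 to 5.79 CPM, and Ostm1 and Clcn7, partners in a chloride transporter of the resorbing membrane, from 109 to 46.8 and from 139 to 75.9 CPM. Other members went the opposite way. Car2, carbonic anhydrase 2, rose from 451 to 927 CPM, Irf8, a repressor of osteoclast formation, from 71.7 to 124 CPM, and Mmp9, a gelatinase, from 0.511 ± 0.101 to 2.65 ± 0.231 CPM.

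Nfatc1, the main transcription factor of osteoclast formation (chromosome 18, 80606205 to 80713071), stood at 44.0 ± 1.49 CPM in LPS and 48.1 ± 8.23 CPM in LPS plus PE-CUR and did not pass (log2 fold change 0.13, edgeR adjusted p = 0.342). It passed as higher without LPS plus PE-CUR replicate 3 (log2 fold change 0.26). Tnfrsf11a, the receptor RANK, rose from 57.6 ± 1.33 to 70.3 ± 7.25 CPM (log2 fold change 0.29, edgeR adjusted p = 0.00715), a call that ended in each of the 3 fits of log2 FPKM (limma adjusted p from 0.0598 to 0.122). Acp5, the acid phosphatase known as TRAP, fell from 12.1 ± 0.835 to 9.70 ± 0.747 CPM (log2 fold change -0.32, edgeR adjusted p = 0.0277). The Acp5 call ended in 4 of the 6 fits that left out a library (edgeR adjusted p from 0.102 to 0.146). Ctsk, the collagenase of osteoclasts, was at 0.485 ± 0.0609 and 0.344 ± 0.0946 CPM and did not pass (edgeR adjusted p = 0.317). In all, 6 rose, 18 fell and 10 did not pass of 34 tested members (6 rose and 18 fell adjusted over the list alone), and the list missed the threshold by a small margin (median -0.31, camera adjusted p = 0.0527). It passed without LPS replicate 1 and under other alternatives, given in the closing section.

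Of 17 proton pump subunits 0 rose, 14 fell and 3 did not pass (0 rose and 14 fell adjusted over the list alone; median log2 fold change -0.41, camera adjusted p = 1.52e-04, and adjusted p = 0.502 with an estimated correlation). Atp6v0a1 fell from 161 to 82.4 CPM, Atp6v1h from 237 to 138 CPM and Atp6v1g1 from 255 to 155 CPM. These pumps acidify lysosomes in all macrophages as well as the resorption pit of osteoclasts. Of 34 lysosome and autophagy genes 1 rose, 22 fell and 11 did not pass (1 rose and 22 fell adjusted over the list alone; median -0.46, camera adjusted p = 5.55e-05, and adjusted p = 0.452 with an estimated correlation). Sqstm1, an autophagy receptor, fell from 3084 to 993 CPM, Gabarapl1 from 152 to 70.0 CPM and the protease gene Ctsl from 1660 to 1120 CPM. Of 18 matrix proteases and inhibitors 2 rose, 10 fell and 6 did not pass (2 rose and 10 fell adjusted over the list alone; median -0.52, camera adjusted p = 0.0291, and adjusted p = 0.452 with an estimated correlation). Mmp12, the macrophage elastase, fell from 5.18 to 0.782 CPM, Mmp19 from 25.0 to 9.67 CPM and Plaur, the urokinase receptor, from 145 to 46.9 CPM, while Ctss rose from 403 to 521 CPM.

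Several genes of the oxidative stress response were lower in LPS plus PE-CUR. Hmox1, which degrades haem (chromosome 8, 75093618 to 75100593), fell 4.23-fold from 4281 ± 349 to 1011 ± 62.4 CPM (log2 fold change -2.08, SE 0.08, edgeR adjusted p = 2.53e-08). Srxn1, which repairs oxidised peroxiredoxins, fell from 404 ± 44.5 to 63.9 ± 3.29 CPM (log2 fold change -2.66, edgeR adjusted p = 1.43e-08) and Cat, catalase, from 282 to 92.0 CPM. Gsr, glutathione reductase, and Tkt, a pentose phosphate enzyme, rose from 62.2 to 91.0 and from 272 to 377 CPM. Of 32 tested targets of the transcription factor NRF2 4 rose, 20 fell and 8 did not pass (4 rose and 22 fell adjusted over the list alone; median -0.55, camera adjusted p = 6.97e-04, and adjusted p = 0.452 with an estimated correlation). Nqo1, another standard target, had between 3 and 17 counts per library and was not tested. Of 20 iron handling and ferroptosis genes 4 rose, 12 fell and 4 did not pass (4 rose and 12 fell adjusted over the list alone; median -0.36, camera adjusted p = 0.0297, and adjusted p = 0.452 with an estimated correlation). Slc11a1, a metal transporter of phagosomes, fell from 146 to 70.9 CPM, and Cp, ceruloplasmin, rose from 12.9 to 87.0 CPM. The call of the iron list ended without LPS plus PE-CUR replicate 1 and without the mitochondrial and 10 most abundant genes.

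Of the lipid uptake, storage and oxidation genes tested, 18 of 26 fell. Plin2, the coat protein of lipid droplets, fell 8.65-fold from 3355 ± 185 to 388 ± 42.3 CPM (log2 fold change -3.11, SE 0.09, edgeR adjusted p = 4.82e-09). Cpt1a, which admits fatty acids to mitochondrial oxidation, fell from 163 to 44.7 CPM, the carnitine carrier gene Slc25a20 from 43.8 to 18.9 CPM and Angptl4 from 14.2 to 3.77 CPM. Fabp5, a fatty acid binding protein, rose from 217 to 419 CPM and Hadhb from 49.2 to 62.7 CPM. Of 26 tested members 4 rose, 18 fell and 4 did not pass (4 rose and 18 fell adjusted over the list alone; median -0.33, camera adjusted p = 0.00120, and adjusted p = 0.452 with an estimated correlation). Of 17 LXR targets and cholesterol efflux genes 2 rose, 10 fell and 5 did not pass (2 rose and 10 fell adjusted over the list alone; camera adjusted p = 0.0521), with Pltp falling from 32.4 to 10.2 CPM and Npc1 from 265 to 134 CPM, and Mylip rising from 0.979 to 6.31 CPM. Of 24 cholesterol synthesis genes 3 rose, 12 fell and 9 did not pass (3 rose and 12 fell adjusted over the list alone; camera adjusted p = 0.135), with Cyp51 and Sc5d lower and Acat2 higher. Of 18 fatty acid synthesis genes 7 rose, 5 fell and 6 did not pass (7 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.776). Fasn, fatty acid synthase, rose from 152 to 250.1 CPM and Acaca from 60.6 to 103 CPM, while the desaturase gene Scd1 fell from 89.9 to 38.3 CPM.

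Of the 2 fixed lists of DNA replication and cell division genes, 1 tested member did not pass and the others rose in LPS plus PE-CUR. All 32 tested members of the S phase list rose (32 rose and 0 fell adjusted over the list alone; median log2 fold change 1.48), among them Tk1, thymidine kinase, from 14.3 ± 1.74 to 85.5 ± 4.0 CPM (log2 fold change 2.58, SE 0.09, edgeR adjusted p = 2.08e-08), Mcm7, a subunit of the replicative helicase, from 35.8 to 123 CPM, and Pole from 25.8 to 90.7 CPM. Of 32 mitosis genes 31 rose, 0 fell and 1 did not pass (32 rose and 0 fell adjusted over the list alone; median 1.81). The mitotic kinase genes Aurka and Aurkb rose from 19.5 to 84.7 and from 16.3 to 73.6 CPM and the checkpoint gene Bub1b from 54.8 to 207 CPM. Camera called both lists (adjusted p = 3.07e-14 and 5.43e-13), and with an estimated correlation the adjusted p = 0.452 for S phase and the adjusted p = 0.452 for mitosis. The list of replication-dependent histones could not be tested, because 0 of its symbols are in the count table, which uses newer names. A search for newer names covered the H2ac, H2bc, H3c and H4c genes and H1f10, but not H1f1 to H1f5. The histone genes it found took 0.00394% ± 0.000375 of counts in LPS and 0.00202% ± 0.0000745 in LPS plus PE-CUR (mean ± SD, n = 3, exact two-sided permutation test p = 0.1, the smallest possible with 3 against 3). Replication-dependent histone transcripts mostly lack a poly(A) tail, so their share also moves with library selection.

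Of 38 nuclear genes of oxidative phosphorylation 36 rose, 0 fell and 2 did not pass (36 rose and 0 fell adjusted over the list alone; median 0.43, camera adjusted p = 1.12e-09, and adjusted p = 0.452 with an estimated correlation). Atp5b and Atp5a1, subunits of ATP synthase, rose from 812 to 1526 and from 516 to 919.9 CPM and Cyc1 from 56.2 to 94.7 CPM. Of 13 mitochondrially encoded transcripts tested, 3 rose, 3 fell and 7 did not pass (3 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.943), with COX2 and ND5 higher. Their share of counts was 3.16% ± 0.231 in LPS and 3.26% ± 0.207 in LPS plus PE-CUR (exact permutation p = 0.7). Of 37 cytosolic ribosomal protein genes 28 rose, 0 fell and 9 did not pass (29 rose and 0 fell adjusted over the list alone; median 0.28, camera adjusted p = 2.28e-06, and adjusted p = 0.452 with an estimated correlation), with Rpl8 rising from 706 to 1043 CPM and Rps2 from 91.7 to 154 CPM. These genes have many processed pseudogenes that can share reads with them. The listed genes took 2.27% ± 0.0341 of counts in LPS and 2.65% ± 0.10 in LPS plus PE-CUR (exact permutation p = 0.1). Of 18 heat shock genes 11 rose, 1 fell and 6 did not pass (11 rose and 1 fell adjusted over the list alone; median 0.56, camera adjusted p = 0.00120, and adjusted p = 0.452 with an estimated correlation), including Hspd1, a mitochondrial chaperone, from 448 to 994 CPM and Fkbp4 from 129.9 to 259.9 CPM. Of 31 glycolysis genes and HIF1A targets 18 rose, 8 fell and 5 did not pass (18 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.134), with Hk2, Eno1 and Pgk1 higher and Ndrg1 and Aldoc lower.

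Of 26 immediate early and MAPK feedback genes 3 rose, 20 fell and 3 did not pass (3 rose and 20 fell adjusted over the list alone; median -0.68, camera adjusted p = 3.84e-04, and adjusted p = 0.452 with an estimated correlation). The phosphatase genes Dusp1 and Dusp5, which switch off MAP kinases, fell from 117 to 13.7 and from 97.7 to 17.9 CPM, and Klf6 from 493 to 202 CPM. Egr3 and Junb rose from 1.43 to 3.48 and from 128 to 186 CPM. Of 30 genes of the ATF4 stress response 10 rose, 15 fell and 5 did not pass (10 rose and 15 fell adjusted over the list alone; camera adjusted p = 0.177). Ddit3, also called CHOP, fell from 162 to 48.0 CPM and Trib3 from 148 to 46.6 CPM, while the serine and glycine synthesis genes Psat1 and Shmt2 rose from 299 to 544 and from 176 to 416 CPM. Of 21 chaperones of the unfolded protein response 3 rose, 8 fell and 10 did not pass (3 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.673), with Ern1 and Dnajb9 lower and Sdf2l1 and Pdia3 higher. Of 24 p53 targets 7 rose, 8 fell and 9 did not pass (7 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.790), with Gadd45a falling from 40.7 to 5.53 CPM, Trp53inp1 also lower and Zmat3 higher. Of 27 apoptosis regulators 6 rose, 8 fell and 13 did not pass (6 rose and 7 fell adjusted over the list alone; camera adjusted p = 0.601), with the death-promoting gene Bcl2l11 lower and the survival gene Mcl1 higher. Of 17 eicosanoid pathway genes 4 rose, 9 fell and 4 did not pass (4 rose and 9 fell adjusted over the list alone; camera adjusted p = 0.162), with Alox5ap and Alox5, which act in leukotriene synthesis, lower. Of 7 metal response genes 1 rose, 3 fell and 3 did not pass (1 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.190), with the zinc transporter genes Slc39a14 lower and Slc39a10 higher. Of 7 nuclear non-coding transcripts 4 rose, 1 fell and 2 did not pass (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.325), with Neat1 lower and Snhg1 and Snhg5 higher.

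Surface and identity genes of macrophages went both ways. Of 21 phagocytosis and scavenger receptor genes 5 rose, 13 fell and 3 did not pass (5 rose and 13 fell adjusted over the list alone; median -0.76, camera adjusted p = 0.0238, and adjusted p = 0.452 with an estimated correlation), with the integrin gene Itgax falling from 15.9 to 1.34 CPM. Of 21 macrophage identity genes 6 rose, 11 fell and 4 did not pass (6 rose and 11 fell adjusted over the list alone; camera adjusted p = 0.292). Adgre1, which encodes F4/80, fell from 85.2 to 26.8 CPM and Ccr2 from 6.57 to 1.08 CPM, while Lyz1, a lysozyme gene with a near-identical neighbour, rose from 574 to 1034 CPM. Of 18 antigen presentation genes 6 rose, 10 fell and 2 did not pass (6 rose and 10 fell adjusted over the list alone; camera adjusted p = 0.673), with the class II genes H2-Eb1 and Cd74 falling from 4.13 to 0.436 and from 643 to 312 CPM and the class I pathway genes Tapbp and Psmb10 rising from 177 to 328 and from 7.25 to 23.6 CPM.

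The 10 largest falls among genes with a mean of at least 5 CPM and no overlap of the groups were those of Car6, Slc16a14, Atp6v0d2, Tenm4, Met, Hid1, Abca8b, Avil, Plet1 and Gbp8, with log2 fold changes from -5.37 to -4.16. Car6, a secreted carbonic anhydrase (chromosome 4, 150187015 to 150201135), fell from 75.3 ± 13.7 to 1.81 ± 0.668 CPM and Met, the receptor of hepatocyte growth factor (chromosome 6, 17463349 to 17573980), from 13.4 ± 0.306 to 0.451 ± 0.0849 CPM. The 10 largest rises were those of Prss35, Clca2, Cd5l, Cryab, Acod1, Ltb, D17H6S56E-5, Ifi44l, Zbp1 and Kif20b. Of these 20 genes, 8 overlap other genes or microRNAs in the annotation (Acod1, Cryab, Kif20b, Ltb, Met, Plet1, Slc16a14 and Tenm4). Ltb, lymphotoxin beta (chromosome 17, 35194507 to 35196305), rose from 9.24 ± 0.653 to 91.4 ± 2.04 CPM (log2 fold change 3.31, SE 0.08, edgeR adjusted p = 1.39e-09). With 3 against 3 libraries, groups fail to overlap by chance in 10% of unchanged genes. LPS plus PE-CUR replicate 1 stood apart for Prss35 (51.3 CPM against 12.1 and 9.50), Clca2 (33.6 against 14.2 and 12.5), Cd5l (17.9 against 7.42 and 5.96) and Cryab (29.3 against 12.6 and 10.9). Prss35 had a log2 fold change of 5.53 over all libraries, 4.38 without that library and 6.48 without LPS replicate 1, and its call ended without LPS replicate 2 or 3 (log2 fold changes 5.27 and 5.24). Cd5l had 4.12 over all libraries and 3.50 without LPS plus PE-CUR replicate 1. Kif20b, a kinesin of cell division, was highest in LPS plus PE-CUR replicate 2 (114 CPM against 30.9 and 44.7). Its log2 fold change of 2.92 became 2.22 without that library, and the call ended without LPS replicate 2 or 3 (2.78 and 2.74).

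Transcripts that macrophages are not known for were also measured, and the genes in this paragraph other than the listed markers were chosen after their values were seen. Alb, the albumin gene, had 49.99, 33.4 and 48.5 CPM of the library total in LPS replicates 1 to 3 and 57.8 in LPS plus PE-CUR replicate 3. It had 1 count in replicate 1 and 0 counts in replicate 2 of LPS plus PE-CUR, so it did not pass between the groups (edgeR adjusted p = 0.634, log2 fold change -1.15). Trf and C3, which liver and macrophages both express, followed the same 4 libraries and were called lower (edgeR adjusted p = 0.0459 and 0.0399). Col1a1 and Col1a2, the genes of type I collagen, had 5.11 and 5.31 CPM in LPS plus PE-CUR replicate 2 and at most 0.464 and 0.278 in the other 5 libraries. The fibroblast and stromal markers summed to 18.3 CPM in that library and to at most 5.84 in the others. A set of 19 bone and connective tissue transcripts, added after seeing the data, summed to 17.3 CPM in LPS plus PE-CUR replicate 2. In the other libraries it summed to between 3.89 and 7.37 CPM. Of its 4 tested members 1 rose and 2 fell (edgeR). The source of these transcripts was not tested. Of 4 tested fibroblast markers 0 rose and 2 fell (edgeR), Pdgfra and Pdgfrb, both under 1 CPM on average. Of 3 tested epithelial markers 2 rose, Krt8 and Krt18, both under 1 CPM on average. Of the B and T cell markers 1 was tested, Lck, a kinase of T cells, which rose from 6.18 to 8.48 CPM. The calls of Pdgfrb, Krt8, Krt18 and Lck ended in at least 1 fit that left out a library, which for Lck was LPS replicate 1 (log2 fold change 0.36). The 10 most abundant genes took 11.5% ± 0.377 of counts in LPS and 10.2% ± 0.677 in LPS plus PE-CUR (exact permutation p = 0.1).

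**Figure D3:**
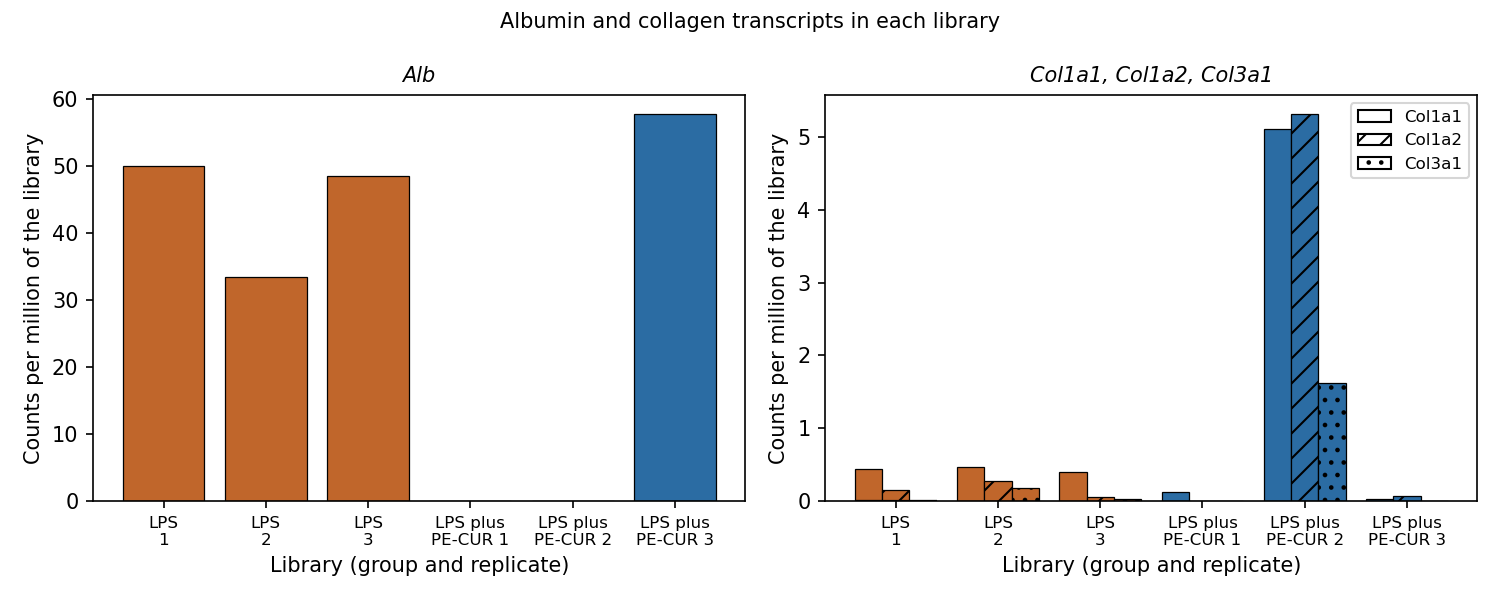
CPM of the library total (y axis, linear) of Alb on the left and of Col1a1, Col1a2 and Col3a1 on the right in each of the 6 libraries (x axis), 1 bar per library and gene. Alb lies between 33.4 and 57.8 in 4 libraries and near 0 in LPS plus PE-CUR replicates 1 and 2, and the collagen genes are highest in LPS plus PE-CUR replicate 2.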

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

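GC and length offsets and the removal of tissue marker genes were chosen after seeing the data. In each of the 19 other fits of single genes, 0 of the 8256 called genes were called in the opposite direction, and 7110 to 8200 were called again. The counts of higher and lower genes moved by over 1.5 times only for at least 2-fold changes with log2(FPKM + 1), which gave 405 higher and 478 lower with the same genes and 403 and 476 without a filter, because the added 1 shrinks the folds of low genes. Of the calls, 48.5% were higher, and 40.7% to 52.5% in the other fits. The replicate numbers did not pair the libraries (correlations of deviations -0.10, -0.18 and -0.05), and with the replicate block 3708 genes were higher and 3953 lower. The number of lists called was 0 with an estimated correlation, 30 with fry for direction and 36 with fry for either direction. The chemokine list, with a median of 0.25 and a camera direction of higher, was called lower by fry for direction and also called by fry for either direction, and the cause was not tested. The proinflammatory list (median -0.35) was called by fry in both forms. The osteoclast list, not called at -0.31, was called lower with library size alone (-0.36), no filter (-0.33), the CPM filter (-0.33), log2(FPKM + 1) (-0.26), log2(FPKM + 0.1) (-0.36), log2(FPKM + 1) without a filter (-0.16), the replicate block (-0.31), GC and length offsets (-0.27), without LPS replicate 1 (-0.31) and both forms of fry (-0.31). Over the fits that left out a library its median lay between -0.32 and -0.23, and the cause was not tested. Over all named genes and alternatives, 76 calls were lost, 3 gained and 3993 outcomes stayed on their side of the threshold. Depth limits genes near 1 CPM, about 30 counts.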

Other observations

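Gene families defined by the stem of the symbol were tested after the data were seen, so these tests were chosen after the result for single genes was known. Of 128 families with at least 10 tested members, camera with the preset correlation called 36, 29 higher and 7 lower in LPS plus PE-CUR. With an estimated correlation camera called 0 families, with 8 at an unadjusted p under 0.05 and a smallest adjusted p of 0.470. Among transcripts for the mitochondrial ribosome, 41 of 49 Mrpl genes were higher and 3 lower (median log2 fold change 0.46, camera adjusted p = 6.72e-07, and adjusted p = 0.470 with an estimated correlation) and 24 of 29 Mrps genes higher. Of the nucleoporin genes 18 of 20 rose and 1 fell (median 0.91, camera adjusted p = 1.52e-06, and adjusted p = 0.470 with an estimated correlation). Higher were also 26 of 36 Ddx RNA helicase genes, 35 of 53 Eif translation initiation genes, 21 of 28 RNA polymerase subunit genes, 9 of 10 Srsf splicing factor genes and all 10 Tomm genes of protein import into mitochondria. In the other direction, 13 of 23 cytochrome P450 genes fell and 0 rose, 23 of 36 Il genes of interleukins and their receptors fell and 4 rose (median -0.52, camera adjusted p = 0.00588, and adjusted p = 0.470 with an estimated correlation), 12 of 19 Dusp phosphatase genes fell, 9 of 14 Tnfrsf receptor genes fell, and 29 of 59 Rab genes of vesicle traffic fell while 10 rose. Of the cytochrome P450 genes, many of which liver expresses, 8 (1 of them called lower) were higher in each of the 4 libraries with Alb than in both others. Without these 8, 12 of 15 fell (median -1.31).

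Of the tests in the next 4 paragraphs, those of single wrong labels, of a shift common to all genes, of GC and length offsets, of liver transcripts counted one by one, of Alb within LPS plus PE-CUR and of other splits of the libraries were chosen after the results were seen. In the libraries labelled LPS plus PE-CUR, NRF2 genes were lower and Tnf, Nos2 and interferon-stimulated genes higher, the reverse of the textbook actions of curcumin. Lipid droplet genes were lower as well, the reverse of what the oil of an emulsion would be expected to do. An exchange of the 2 groups' labels is thus a candidate explanation. By contrast, Ptgs2, Cxcl2, Il6, Il1a and Il1b were lower, as the labels would have it (13 lower and 6 higher in the proinflammatory list). An oil emulsion would be expected to raise fatty acid oxidation and PPAR target genes, so 18 further genes of this kind were examined. Their median log2 fold change was -0.21 (SD 0.84), with 9 lower, 4 higher and 5 not passing. This meets the bound set beforehand for an exchange, a median below 0 and more falls than rises. The median lies near 0 with members going both ways. The 4 rises were at most 0.44 (Acad10), whereas the 9 falls reached -2.55 (Acot1). An exact two-sided binomial test of 9 against 4, which was not part of that bound, gave p = 0.267. A lowering of these genes by PE-CUR would give the same values, so an exchange and a response cannot be told apart in this design. The tables argue against single wrong labels, since the lowest correlation within a group lay 0.0296 above the highest between groups. For a shift common to all genes, the mean log2 CPM of the lower set (lipid and NRF2 lists) was subtracted from that of the higher set (interferon list, Tnf, Nos2). The difference was at least 1.35 higher in each LPS plus PE-CUR library than in any LPS library (larger SD within a group 0.14). A common shift leaves this difference as it is, so it cannot by itself part the sets. The sets were chosen for their opposite directions in these libraries, so the difference restates the pattern and is no separate test. How far each set moved alone is not decided by it. The 0 sign changes of 3 list medians under 3 other scalings decide nothing, as these moved the medians by at most 0.06.

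Albumin transcripts appeared in 4 of the 6 libraries, and carry-over of liver RNA is a candidate explanation. Liver transcripts written down before they were examined, 34 in the table, summed to at least 3.31 times more in each of the 4 libraries than in either other library. That ratio fell between both bounds set beforehand, 10 for and 3 against, so by that test the explanation stays open. Ambp alone held 14.7 of the 16.4 CPM summed in LPS plus PE-CUR replicate 1. Leaving out Ambp and Serpinc1 was not set beforehand. Without them the lowest sum of the 4 libraries was 127 times the highest of the other 2 (47.3 against 0.372 CPM). Of the 34 transcripts, 21 had no read in either of those 2. Counting one by one was adopted only after the ratio of 3.31 was seen. By that count 32 of the 34 were higher in each of the 4 libraries than in both others (the exceptions were Ambp and Mup20), as liver RNA would give. A response to PE-CUR shared by its 3 libraries would give them 1 level, which they did not have. The liver transcripts summed to 82.1 CPM in LPS plus PE-CUR replicate 3, to 16.4 and 13.3 in replicates 1 and 2, and to 54.4 to 67.0 in LPS. A response that differed between cultures stays open. The ratio of Alb in LPS plus PE-CUR replicate 3 to replicates 1 and 2 pooled was at least 699 (lower bound of the exact 95% Poisson interval). That ratio allows for counting error only and not for the spread between cultures, and it rests on 1 library with Alb in that group.

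Genes of DNA replication and mitosis were higher in LPS plus PE-CUR, and long AT-rich transcripts differed between libraries within groups, with a median deviation of 0.14 (log2) in LPS plus PE-CUR replicate 2 and -0.11 in replicate 1 over 572 genes. With GC and length offsets the smaller of the medians of the S phase and mitosis lists was 1.53, and over the 6 fits that left out 1 library it was at least 1.44, both above 1. The tables thus argue against GC and length bias and against 1 library as the whole cause. A difference in growth between the groups, such as a lighter growth arrest by LPS, may account for it. Cell numbers were not analysed here, and without untreated cells a growth arrest by LPS cannot be seen. The share of counts in the histone genes found went the other way, 0.00394% in LPS and 0.00202% in LPS plus PE-CUR. That share also moves with library selection. The exchange of labels weighed above stays open for this pattern too.

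Splitting the 6 libraries in the 10 possible ways, 1 split, the real one, gave 8256 genes at an adjusted p under 0.05 and 2320 at least 2-fold, and the highest of the others gave 0 in both (edgeR, with 21 to 244 genes at an unadjusted p under 0.05). For lists, 2 of the 10 splits, the real one included, called at least 14, and the highest of the others called 17. With 10 splits no share can fall under 0.05. Each of the 9 other splits keeps part of the difference between the groups, so their counts are not those of libraries without a difference.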
